A study of Drosophila melanogaster with 16 samples.

How the data were processed

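RNA sequencing of sorted cells was used from 16 libraries of 7 cell types: 4 of L3 and 2 each of L1, L2, L4, L5, R7 and R8. Per the labels' protocols, cells were sorted by flow cytometry and libraries were made from total RNA. The authors deposited 1 table of RPKM values with 15682 genes and 1 column per library. Per the submitters' processing notes, reads were aligned with TopHat to genome build BDGP5. Versions, the counting tool, the annotation release and the strand setting are not given in the sources used here. No sample column was left unused.

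Values were used as deposited, without further scaling between libraries. Read depth was recovered from the steps between low values and the gene lengths of the current annotation. It ran from 47.05 to 153.6 M reads, and 70.2 to 74.2% of values of 20 reads or fewer came out within 0.05 of a whole number, so the fits of the report did not use reads. Recovered reads served for 1 alternative, the depth, the mitochondrial share and the comparison of replicates with sampling noise. Mitochondrial genes held 3.96 to 14.61% of the reads. No coordinates were used, since the reference at hand was a later build. Of the gene IDs, 15002 matched current symbols, 3 entries had no symbol and 23 symbols stood on 2 IDs. Symbols in the text are those of the table or the current ones, with both given for genes named by rule where they differ. Overlap of exons with other genes in the current annotation leaves reads uncertain for CG13739 (42.5% of exonic bases), Traf4 (26.8%), Ir76a (14.1%) and CG12493 (10.2%), among the genes named by rule, as well as for those marked in the report. Copies of Hsp70 share reads.

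Genes with an RPKM of at least 1 in at least 2 libraries were tested (9346 genes). Values were taken as log2(RPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 7 types and a trend in the variance. Contrasts were the mean of R7 and R8 against the mean of L1 to L5, R7 against R8, and each lamina type against the mean of the other 4. F-tests covered L1 to L5 and all 7 types, and every pair of types was compared. P-values were adjusted by Benjamini and Hochberg's method and called under 0.05. The plan, written before the data were examined, assumed read counts and named this limma test for normalized values. The values proved to be RPKM, so the planned count-based test and its alternatives were not run. In data simulated with a dispersion of 0.05, the test recovered 88, 35, 89 and 60 of 100 genes changed 2-fold for R against L, R7 against R8, L3 and L1, and 92, 89, 95 and 92 of 100 changed 4-fold. It called 8, 5, 12 and 9 of the unchanged genes among 8055, 8065, 8071 and 8074 run. The dispersion was the same for every gene and type and was not estimated from these libraries, so these rates may not carry over to them.

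The 25 gene lists fixed in the plan were dpr, DIP, beat and side, photoreceptor identity, R7 and R8 fate, R1 to R6, phototransduction, lamina transcription factors, transmitters, synaptic release, pan-neuronal genes, guidance and surface genes, ion channels, neurotransmitter receptors, ecdysone response, glia, blood cells, cone and pigment cells, fat body, proliferation, medulla neuron factors, stress, sex, ribosomal and mitochondrial genes. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Counts of called genes were also taken with p-values adjusted over the list alone. Of the listed names, Cask, nAChRalpha4 and Dop1R2 matched nothing in the table. The planned aliases of side-II and side-V were wrong and were replaced by current symbols, and the list of medulla neuron factors includes dm, a wrong choice.

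Genes were named by a rule in the plan. For R against L and for R7 against R8 it took the 10 genes with the greatest log2 difference each way among genes called, with a mean of at least 10 RPKM in the higher group and every library of that group above every library of the other. For each lamina type it took the 4 greatest upward. Members of the lists for dpr, DIP, beat and side, photoreceptor identity, lamina factors, transmitters, phototransduction, R7 and R8 fate, and guidance could be named as well, and up to 4 members of each other list. Family and gene choices made later are stated where they occur.

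Alternatives named in the plan were quantile normalization, no filter on low values, a pseudocount of 0.1, a 2-fold threshold, replicate number as a block, 2 pooled classes for R and L, fits on the R7 and R8 libraries or the lamina libraries alone, and leaving out each of the 16 libraries. Alternatives chosen after seeing the data were voom on recovered reads, leaving out L3 libraries, and leaving out genes that follow the Osiris family. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.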

Results

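RNA was sequenced from 7 types of neuron of the developing fruit fly (Drosophila melanogaster) visual system, each isolated by flow cytometry from dissociated pupal tissue. R7 and R8 are the inner photoreceptors, which detect light and send their axons into the medulla. L1 to L5 are the lamina neurons, which carry visual signals from the lamina to the medulla. The 16 libraries comprised 4 of L3 and 2 of each other type, and each library was 1 column of RPKM values (reads scaled to gene length and library depth) for 15682 genes. The series title frames the study as a question about cell surface proteins of the immunoglobulin superfamily, and about complementary ligands and receptors in synaptic partners. The medulla neurons that receive these axons were not analysed here, so the comparisons are between the presynaptic types.

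The labels gave conflicting ages. The age field gave 24 h after pupal formation for L1, 35 h for L2, 40 h for L3, 45 h for L4, 53 h for L5, 65 h for R7 and 96 h for R8, whereas the dissection protocol gave 40 h for every library. The headings of the lamina columns also carried 40 h, and those of R7 and R8 gave no age. The series design text speaks of the same times as the age field, but for R cells. If the age field holds, age and cell type cannot be separated in any of the comparisons. Depth, recovered from the steps between low values, ran from 47.05 M reads in L5 replicate 1 to 153.6 M reads in R8 replicate 1. At those depths 3 reads on a gene of 2 kb correspond to an RPKM of 0.00977 to 0.0319, for counting error only.

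The first 2 principal components separated photoreceptors from lamina neurons, and L1 and L2 from L3, L4 and L5. The first principal component of log2(RPKM + 1) held 42.4% of the variance and placed the 4 photoreceptor libraries between 84.5 and 90.3, with the 12 lamina libraries between -50.6 and -10.9. The second component held 15.6% and placed L1 and L2 between -52.7 and -46.0, with L3, L4 and L5 between 6.64 and 37.3. On these 2 axes L4 replicate 2 lay nearer to the L5 libraries than to L4 replicate 1. The third component (11.7%) placed L4 between -31.1 and -26.4 and L5 between -52.2 and -47.2. On it L3 replicates 1 and 2 lay at 38.8 and 39.2, and L3 replicates 3 and 4 at 26.6 and 26.5. Mitochondrial genes held 4.17 and 3.96% of the reads in L3 replicates 1 and 2, and 14.61 and 9.6% in replicates 3 and 4. Replicates correlated across genes with a Pearson r of 0.940 (L4) to 0.996 (L1), and genes are not independent replicates. No 2 libraries of a type agreed within the sampling noise of the recovered reads. Chi-square per gene ran from 47.5 for R7 to 1224.8 for L3 replicates 1 and 3. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The fit gave each gene a common variance over all 7 types. The p-values for R7 against R8 therefore also draw on the spread within the lamina types. Means are given ± SD over the 2 libraries of a type (4 for L3), log2 differences are on the log2(RPKM + 1) scale, and adjusted p-values are limma's.

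**Figure D1:**
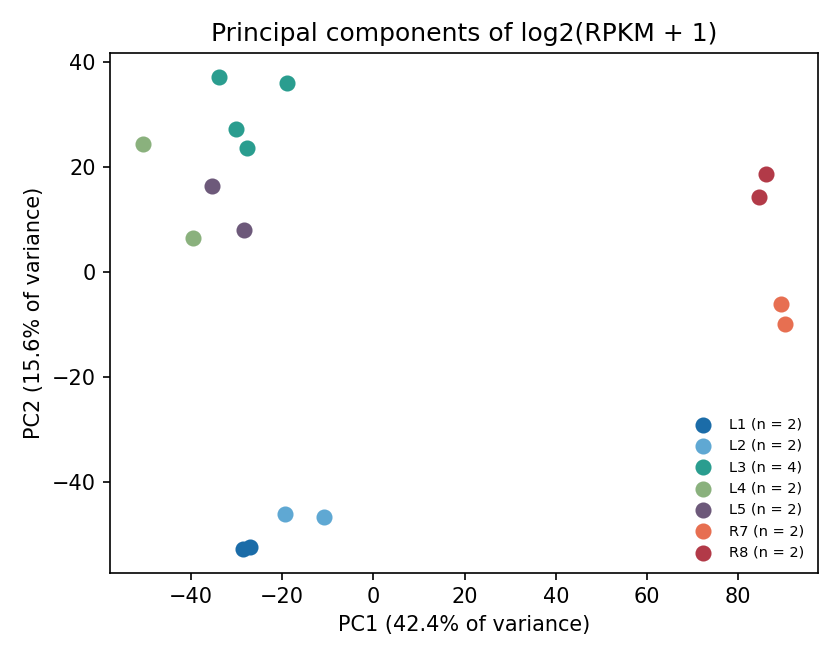
Each point is 1 library, coloured by cell type, placed on the first (x axis, 42.4% of variance) and second (y axis, 15.6%) principal components of log2(RPKM + 1). The 4 photoreceptor libraries lie between 84.5 and 90.3 on the x axis and the 12 lamina libraries between -50.6 and -10.9.

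Most genes tested of light detection and eye identity were higher in photoreceptors. Most neurotransmitter receptor genes and lamina transcription factor genes tested were higher in lamina neurons. The surface glycoprotein gene chp (FBgn0000313), which photoreceptors need to build the light-sensing organelle, averaged 1345 ± 37.2 RPKM in R7 and 981 ± 151 in R8 against 2.07 to 45.5 in the lamina types. The peroxidase gene Pxn (FBgn0011828), whose product acts in the extracellular matrix, averaged 14.2 to 221 RPKM in the lamina types against 0.393 ± 0.176 in R7 and 0.302 ± 0.0381 in R8. Of 9346 genes tested, 2963 were higher in R neurons and 2821 were lower.

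The 10 genes with the greatest excess in R neurons under the naming rule included 6 of the visual cascade or its membrane. The light-gated cation channel trp (FBgn0003861) reached 720.4 ± 109.6 RPKM in R7 and 310.4 ± 90.7 in R8, a log2 difference of 6.81 ± 0.32 (SE) from the lamina mean (adjusted p = 1.17e-09). Eye protein kinase C inaC (FBgn0004784) was higher by 6.97, the arrestin Arr2 (FBgn0000121) by 6.80, the myosin kinase ninaC (FBgn0002938) by 6.75 and the scaffold inaD (FBgn0001263) by 6.71, with chp at 7.14. The tetraspanin Tsp47F (FBgn0033629) stood at 608 ± 20.2 RPKM in R7 and 588 ± 12.8 in R8. The uncharacterised genes CG30154 (FBgn0050154), CG34138 (FBgn0083974) and CG31636 (FBgn0051636) completed the group, with log2 differences of 8.29, 7.89 and 6.95. CG30154 differed between the photoreceptors too, with 403 ± 21.2 RPKM in R7 and 2073 ± 462 in R8. In all, 1023 genes met the conditions of the rule in this direction.

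All 10 genes of the photoreceptor identity list were higher in R neurons, also when adjusted over the list alone (camera adjusted p = 3.22e-06, and adjusted p = 0.0579 with an estimated correlation). The homeobox genes Pph13 (100.3 ± 0.329 RPKM in R7, 0.125 to 2.77 in lamina types) and oc (41.2 ± 0.831, 0.244 to 2.67) and the zinc finger gene gl (109 ± 4.53, 1.29 to 5.97) were among them. Of 17 phototransduction genes tested, 14 were higher and 2 lower, and likewise 14 and 2 adjusted over the list alone (camera adjusted p = 3.95e-05, and adjusted p = 0.118 with an estimated correlation). The 2 lower genes were the phospholipase C gene norpA (-1.07) and the channel gene trpl (-1.72). Genes for recycling and sensing histamine, the photoreceptor transmitter, were higher in R: the carcinine transporter CarT by 4.37, the hydrolase t by 4.21 and the histamine-gated chloride channel HisCl1 by 5.06 log2 units. Hdc, the enzyme that makes histamine, reached 1.999 ± 0.158 RPKM in R7 and 3.59 ± 0.142 in R8. Over the 41 genes at 100 RPKM or more in R neurons and at least 50 times the L1 and L2 levels, the median level in L3 was 3.91% of that in R neurons, against 1.10% in L4 and 0.765% in L5. The selection itself holds L1 and L2 under 2%, so they are no comparison.

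Of 30 receptor genes tested, 21 were lower in R neurons and 4 higher, the same counts when adjusted over the list alone (camera adjusted p = 1.06e-05, and adjusted p = 0.126 with an estimated correlation). The nicotinic subunit genes nAcRbeta-96A (FBgn0004118; 93.0 to 207 RPKM in lamina types, 2.04 to 2.48 in R types) and nAcRbeta-64B (153 to 445 and 7.21 to 8.52) differed by -5.58 and -5.01 log2 units. GluClalpha (FBgn0024963), a glutamate-gated chloride channel, had a log2 difference of -5.02. CG3822 (FBgn0038837; KaiR1D), a kainate-type glutamate receptor, had 149.7 to 512 RPKM in lamina types and 2.66 to 4.07 in R types. The 4 receptor genes higher in R neurons were HisCl1, Oamb (2.25), GABA-B-R3 (2.13) and 5-HT1B (1.02), the last 3 named after their values were seen. Of 17 ion channel genes 10 were lower and 2 higher, also over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.656 with an estimated correlation). The hyperpolarisation-activated channel Ih (-4.02), the potassium channel Sh (-2.65) and the channel subunits unc80 (-2.55) and unc79 (-2.28) were lower. The 2 higher, named after their values were seen, were the potassium channel eag (1.63) and the sodium channel para (0.95).

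Among the other genes the rule named for lamina neurons, the homeobox gene scro (FBgn0028993) had 63.6 to 104.3 RPKM and the forkhead gene slp1 (FBgn0003430) 18.4 to 478 across the 5 types. Slp1 was high in L1, L2 and L5 (437, 322 and 478 RPKM) and low in L3 and L4 (18.4 and 19.0). The cyclic nucleotide-gated channel homologue cngl (FBgn0263257), the metalloprotease gene tok (FBgn0004885) and the uncharacterised CG43647 (FBgn0263656) and CG7781 (FBgn0032021) differed by -5.78, -5.26, -5.37 and -5.02 log2 units. In this direction 740 genes met the conditions of the rule. Of 13 lamina transcription factor genes tested, 10 were lower in R neurons and 1 higher, over the list alone as well (camera adjusted p = 0.000215, and adjusted p = 0.118 with an estimated correlation). The factor gene dac was at 0.152 to 0.279 RPKM in R types, at 0.264 in L2 and at 59.9 to 134 in the other lamina types. The homeobox gene hth was the higher one (0.82).

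Cholinergic genes followed the lamina types other than L1. ChAT and VAChT, which make and package acetylcholine, were lower in R (log2 differences -3.09 and -3.76), and in L1 they stood at 0.814 ± 0.221 and 0.638 ± 0.133 RPKM. These 2 genes share a locus in flies. The vesicular GABA transporter VGAT had 8.05 to 13.3 RPKM in lamina types, while Gad1, which makes GABA, stayed at 0.00800 to 0.325. Of 13 transmitter genes tested, 4 were higher and 7 lower in R (8 lower adjusted over the list alone). The vesicular glutamate transporter VGlut was lower in R on account of L1, at 214 and 220 RPKM. Its R libraries (1.94 to 3.40 RPKM) lay above those of L2 (0.672 and 0.940) and L5 (0.227 and 0.481). They overlapped L3 (2.40 to 11.8) and L4 (1.63 and 2.75).

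Ribosomal protein genes were higher in R neurons in 67 of 87 cases and lower in 4 (68 and 4 adjusted over the list alone; camera adjusted p = 9.55e-06, and adjusted p = 0.724 with an estimated correlation). The 4 lower, named after their values were seen, were RpLP2, RpL24, RpL34b and RpS19b. The call of RpL24 ended without any single R library (adjusted p from 0.0535 to 0.0811) and that of RpLP2 without R7 replicate 1 (0.0707) or R8 replicate 1 (0.0732), so 2 were lower without either of these 2 libraries. After quantile normalization 47 were higher and 10 lower. Of 70 guidance and surface genes, 43 were lower in R and 18 higher, also over the list alone (camera adjusted p = 0.00381, and adjusted p = 0.601 with an estimated correlation). Nrx-1, a presynaptic adhesion gene, was at 411 to 614 RPKM in lamina types and 35.8 to 59.0 in R types, and kirre, an adhesion gene of the nephrin family, at 261 to 536 and 19.5 to 52.9. In R neurons fred (4.16), klg (4.02) and otk (2.83) were higher. The excess of klg rested on L1, L2 and L5, at 0.255 to 1.86% of its mean R level. In L3 it stood at 99.2% of that level and in L4 at 60.6%. The remaining lists gave no shift by camera in this comparison: higher and lower counts were 2 and 8 of 17 for synaptic release, 2 and 4 of 10 for pan-neuronal genes, 2 and 6 of 13 for ecdysone response, 3 and 2 of 9 for glia, and 3 and 1 of 9 for cone and pigment cells. They were 3 and 8 of 15 for stress, 3 and 3 of 11 for medulla neuron factors (3 and 2 over the list alone), 8 and 3 of 23 for mitochondrial genes (6 and 2), 2 and 2 of 5 for blood cells (2 and 3), 1 and 1 of 6 for fat body, 3 and 0 of 5 for proliferation, 1 and 3 of 8 for sex genes, and 1 and 1 of 3 for R1 to R6 genes. Counts over the list alone were equal where none is given. Without R7 replicate 1, 1 gene was higher for synaptic release, 1 for ecdysone response and 5 for mitochondrial genes, with 1 lower for glia. Without R8 replicate 2, 1 was higher for ecdysone response and 5 for mitochondrial genes. Without R8 replicate 1, 1 was higher for synaptic release and 1 lower for glia, and without R7 replicate 2, 1 was lower for glia. The R1 to R6 gene lower in R was not called without L1 replicate 2, R7 replicate 1 or 2, or R8 replicate 2. Without L3 replicate 4 or L4 replicate 2, 2 fat body genes were lower, and without L4 replicate 2, 1 proliferation gene was. For glia and for R1 to R6 genes, the list's median log2 difference was negative (-0.01 and -0.18) and its mean positive (0.60 and 0.08), with camera in the direction of the mean.

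Over all 7 comparisons, 45 of 175 list shifts passed at camera's preset correlation of 0.01 and 0 passed with a correlation estimated from the data (22 at an unadjusted p under 0.05; lowest adjusted p = 0.0530), whereas fry, which asks whether a list's genes move one way on balance, called 85. Requiring more than a 2-fold difference left 1420 genes higher and 1196 lower in R neurons, and a fit that pooled the libraries into 2 classes left 1842 lower. Without the 4 L3 libraries, a choice made after seeing the data, 3218 were higher and 3066 lower.

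**Figure D2:**
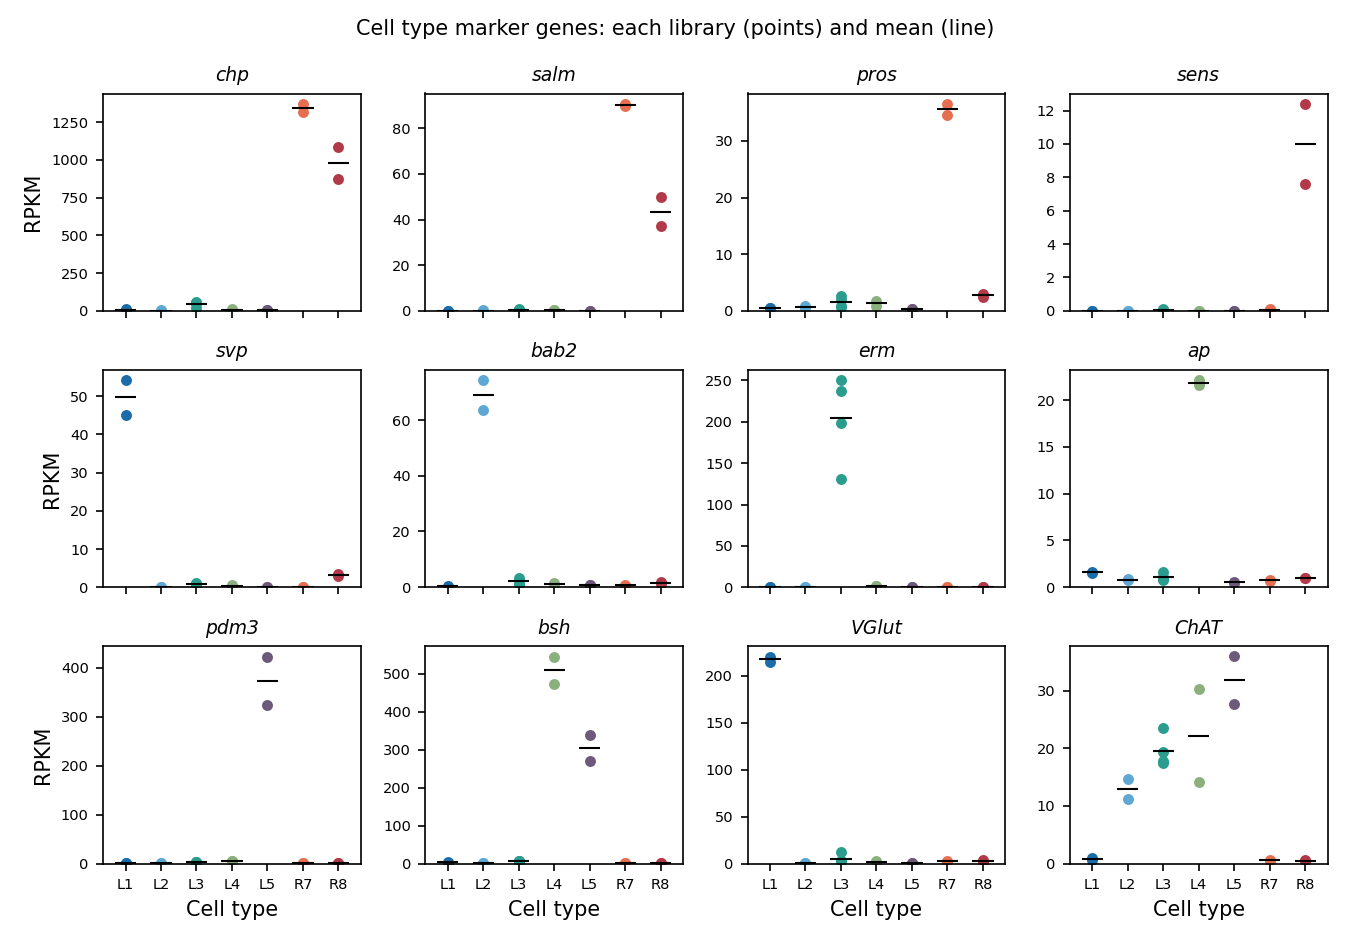
RPKM (y axes, linear, each from 0) of 12 genes in each library (points) and the mean of each cell type (lines) for the 7 cell types on the x axes (n = 4 for L3, 2 for the others). The genes chp, salm, pros and sens mark photoreceptors, with sens at 9.99 RPKM in R8 and 0.0749 in R7, and svp, bab2, erm, ap, pdm3, bsh, VGlut and ChAT differ among the lamina types.

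R7 and R8 differed in the transcription factors that set photoreceptor subtype and in genes such as the ecdysone-inducible ImpL1 and ImpE2, which were higher in R8. The R8 determinant sens, a zinc finger gene, had 9.99 ± 3.41 RPKM in R8 and 0.0749 ± 0.0524 in R7. The R7 factor genes pros (35.6 ± 1.39 RPKM in R7, 2.75 ± 0.312 in R8), run (11.2 ± 1.502, 0.953 ± 0.0191) and ss (8.29 ± 0.587, 1.69 ± 0.257) were higher in R7 by 3.29, 2.64 and 1.79 log2 units. Of 9346 genes, 299 were higher in R7 and 667 in R8.

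Of 11 R7 and R8 fate genes tested, 5 were higher in R7 and 4 in R8 (6 and 4 adjusted over the list alone), and in R neurons as a class 8 were higher and 3 lower than in L (camera adjusted p = 0.00245, and adjusted p = 0.134 with an estimated correlation). The others higher in R7 were salm (1.05) and gogo (0.97), a guidance receptor, and those higher in R8 were sens, the netrin gene NetB (-1.17), its receptor gene fra (-0.88) and the layer-targeting gene caps (-0.99). The call of salm ended without R8 replicate 2 (adjusted p = 0.0539), those of gogo and caps without R7 replicate 1 (0.150 and 0.102) or R8 replicate 2 (0.162 and 0.0562), and that of NetB without R7 replicate 2 (0.0833) or R8 replicate 2 (0.0865). That of fra ended without any single library of L1, L2 or R7, L3 replicate 1 or 2, or R8 replicate 1 (adjusted p from 0.0510 to 0.460). The counts were 4 and 2 without R7 replicate 1, 5 and 2 without R7 replicate 2 and 3 and 2 without R8 replicate 2. After quantile normalization 5 were higher in R7 and 1 in R8. Boss, the ligand that R8 presents to R7 in the larval eye disc, was not called different (142 ± 20.1 and 166 ± 24.7 RPKM, and adjusted p = 0.937). The ultraviolet opsin Rh3 (FBgn0003249) had 20.999 ± 0.558 RPKM in R7 and 0.693 ± 0.152 in R8. The R8 opsin Rh6 had 1.74 ± 0.0129 RPKM in R8 and 0.0578 ± 0.0436 in R7 (adjusted p = 0.00585, and 0.0548 without R7 replicate 2), while Rh5, the other R8 opsin, stood at 0.213 ± 0.0239 in R8 and Rh4, the other R7 opsin, at 1.02 ± 0.0452 in R7.

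The rule named 9 further genes higher in R7, of 181 that met its conditions. CG9150 (FBgn0031775) reached 2114 ± 28.9 RPKM in R7 and 27.8 ± 1.09 in R8, a log2 difference of 6.20 ± 0.49 (SE, and adjusted p = 4.11e-06). CG14500 (FBgn0034318) was at 77.5 ± 11.3 RPKM in R7, 0.340 ± 0.00459 in R8 and at most 0.0194 in a lamina type. The RNA-binding gene blanks (FBgn0035608; 5.54), HP6 (FBgn0031613; 4.68), a relative of heterochromatin proteins, the ionotropic receptor gene Ir76a (FBgn0260874; 4.01) and the cuticle protein gene Cpr92F (FBgn0038819; 3.86) followed. CG4783 (FBgn0038756), CG33639 (FBgn0053639) and CG12493 (FBgn0035571) differed by 5.07, 3.87 and 3.54 log2 units.

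Of 309 genes that met the conditions for R8, the 10 named included 2 hormone-response genes, a chitinase gene and an Osiris family gene. ImpL1 (FBgn0001256) and ImpE2 (FBgn0001254), first found as ecdysone-inducible genes of imaginal discs, had 1492 ± 146 and 89.3 ± 3.42 RPKM in R8 against 5.87 ± 5.42 and 0.282 ± 0.183 in R7 (adjusted p = 1.88e-06 and 2.31e-06). The chitinase gene Cht5 (FBgn0038180) was at 291 ± 98.5 and 3.52 ± 1.39 RPKM, the Osiris family gene Osi9 (FBgn0037416) at 678 ± 450.0 and 11.3 ± 12.2, and the neuropeptide-like precursor Nplp3 (FBgn0042201) at 158 ± 36.1 and 0.493 ± 0.663. CG14490 (FBgn0034281), CG34247 (FBgn0085276), CG13023 (FBgn0036677), CG13081 (FBgn0032804) and CG11997 (FBgn0037662) differed by -7.65, -7.63, -7.16, -6.84 and -5.98 log2 units. In the current annotation 37.0% of the exonic bases of CG14490 overlap a gene on the other strand, so its value is uncertain. The genes named for R8 were found in lamina types as well, ImpL1 at 19.1 to 362 RPKM, ImpE2 at 3.90 to 49.5, Cht5 at 5.69 to 48.4, Osi9 at 11.6 to 103.8, Nplp3 at 1.12 to 11.4, CG14490 at 0.971 to 8.64, CG34247 at 5.62 to 191, CG13023 at 13.2 to 285, CG13081 at 1.82 to 30.3 and CG11997 at 4.93 to 75.6. Of 17 Osiris genes tested, a family chosen after seeing the data, 8 were higher in R8. Their median was 17.5 and 27.3 RPKM in the R8 libraries and 0.270 and 1.33 in the R7 libraries, and it ranged from 0.625 to 49.9 among the 4 L3 libraries.

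**Figure D3:**
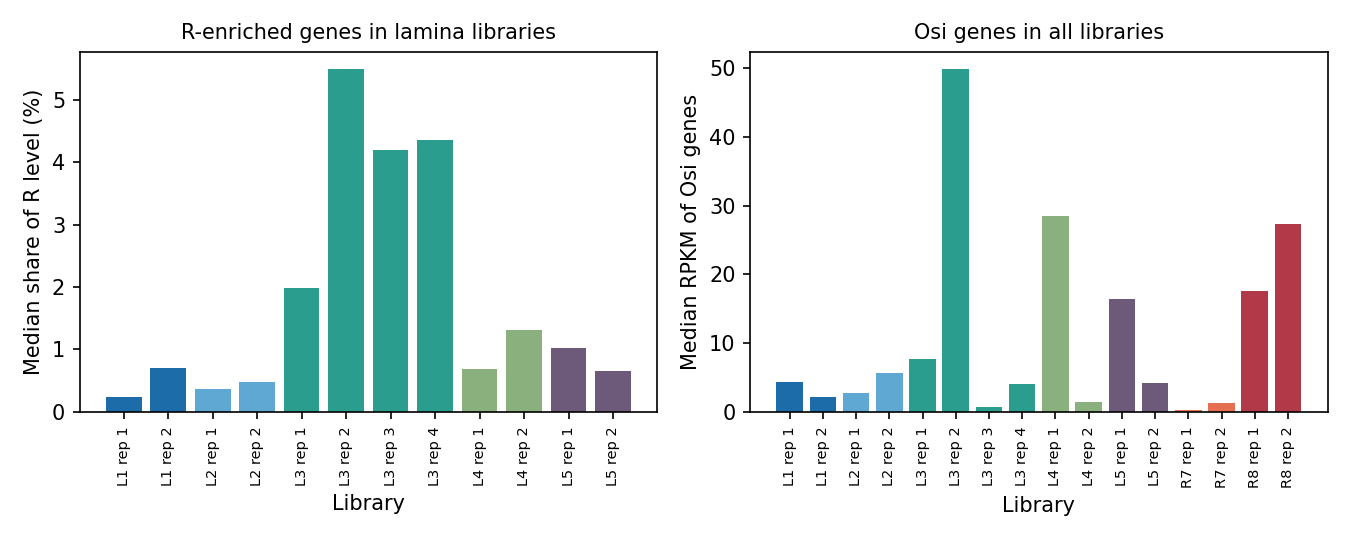
Left, median level (y axis, percent of the mean R level, bars from 0) of 41 genes enriched in R neurons in each lamina library (x axis), with L3 at 1.99 to 5.50% and the others at 1.30% or less, L1 and L2 being held low by the selection of the genes. Right, median RPKM (y axis, bars from 0) of 17 Osiris genes in each of the 16 libraries (x axis), from 0.270 in R7 replicate 1 to 49.9 in L3 replicate 2.

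Nicotinic receptor genes separated the 2 photoreceptors by 1 subunit in particular: gfA (nAChRalpha7) was at 983 ± 12.3 RPKM in R8 and 32.5 ± 2.50 in R7. Of 30 receptor genes 6 were higher in R8 and 0 in R7, among them 5-HT1B (-2.08) and Oamb (-1.07), and 3 were without R7 replicate 1, R8 replicate 1 or R8 replicate 2. After quantile normalization 3 were higher in R8 and 1 in R7. Several lists moved together toward R8 at the preset correlation but not with an estimated one. Mitochondrial genes in total were not among the rises, with 7.4 and 7.03% of the reads in the R7 libraries and 8.32 and 5.8% in the R8 libraries. Of 23 mitochondrial genes 6 were higher in R8 and 0 in R7 (11 and 0 over the list alone; camera adjusted p = 3.38e-05, and adjusted p = 0.216 with an estimated correlation), 4 of them transfer RNA genes. Without R7 replicate 2 the count was 2. Of 15 stress genes 2, Hsp68 and kay, were higher in R8 (9 over the list alone; camera adjusted p = 9.43e-05, and adjusted p = 0.451 with an estimated correlation), but the call of Hsp68 ended without R7 replicate 1 (adjusted p = 0.110) or R8 replicate 2 (0.0890), and that of kay without any single library except L3 replicate 3 or 4 and those of L4 (up to 0.423). Without L3 replicate 4, L4 replicate 1 or L4 replicate 2, 5 stress genes were higher in R8. Of 70 guidance and surface genes 11 were higher in R8 and 5 in R7 (20 and 7 over the list alone; camera adjusted p = 0.0257, and adjusted p = 0.677 with an estimated correlation), among them the receptor phosphatase Ptp99A (-2.07) and the Toll-related receptor Tollo (-1.14) in R8. Counts in R8 and R7 were 3 and 0 without R7 replicate 1, 5 and 1 without R7 replicate 2, 6 and 1 without R8 replicate 1, 4 and 0 without R8 replicate 2, and 9 and 2 without any single library of L1 or L2. After quantile normalization the counts were 6 and 3.

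Ecdysone response genes were higher in R8 in 2 of 13 cases (4 over the list alone; camera adjusted p = 0.0480, and adjusted p = 0.677 with an estimated correlation), namely Eip78C (-1.13) and Eip63E (-2.04). Glial genes were higher in R8 in 3 of 9 cases, also over the list alone (camera adjusted p = 0.0480, and adjusted p = 0.677 with an estimated correlation), namely axo (29.9 ± 0.925 RPKM in R8, 7.48 ± 0.379 in R7), moody (3.48 ± 0.380, 0.791 ± 0.195) and wrapper (2.08 ± 0.662, 0.0343 ± 0.0136), the last not called without R7 replicate 1, R7 replicate 2 or R8 replicate 2 (adjusted p = 0.102, 0.0956 and 0.157). Of 3 genes of R1 to R6, 2 were higher in R8 (3 over the list alone; camera adjusted p = 0.00263, and adjusted p = 0.216 with an estimated correlation), svp at 3.21 ± 0.258 RPKM and B-H1 at 1.45 ± 0.217, the latter not called without R7 replicate 1, R7 replicate 2 or R8 replicate 2 (adjusted p = 0.0638, 0.0999 and 0.114). The opsin of R1 to R6, ninaE, was at 0.0950 ± 0.0301 RPKM in R7 and 0.139 ± 0.0985 in R8. Counts higher in R7 and in R8 were 1 and 2 of 17 for phototransduction (1 and 3 over the list alone), 0 and 2 of 10 for photoreceptor identity, 0 and 2 of 13 for lamina factors, 3 and 0 of 17 for synaptic release (3 and 1), 1 and 0 of 9 for cone and pigment cells (1 and 5), and 2 and 1 of 19 for beat and side genes (2 and 2). They were 1 and 1 of 5 for blood cells, 1 and 0 of 6 for fat body, 0 and 1 of 5 for proliferation (0 and 2), 0 and 2 of 11 for medulla neuron factors, 1 and 0 of 8 for sex genes, and 0 and 1 of 87 for ribosomal genes (0 and 0). Leaving out single libraries moved the counts of these lists to between 0 and 3. By limma 0 of 13 transmitter, 0 of 10 pan-neuronal and 0 of 17 ion channel genes differed (1, 3 and 1 at an unadjusted p under 0.05), and by voom on recovered reads 0, 1 and 0. The list's median and mean log2 difference had opposite signs for phototransduction (-0.41 and 0.01), fat body (-0.01 and 0.45) and sex genes (-0.03 and 0.28).

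Quantile normalization moved the R7 share of the calls from 31.0% (299 and 667 genes) to 41.5% (386 and 544), and a fit on the 4 photoreceptor libraries alone called 1160 genes higher in R7 and 1319 in R8. The R7 count was 136 without R7 replicate 1, 137 without R7 replicate 2, 155 without R8 replicate 1 and 141 without R8 replicate 2, and the R8 count was 390, 387 and 370 without R7 replicate 1, R7 replicate 2 and R8 replicate 2. Leaving out genes whose deviations followed the Osiris genes, a choice made after seeing the data, gave 275 and 523.

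Lamina neurons divided by transcription factor, transmitter and surface gene. Among L1 to L5, 4164 genes differed, and 11 of 13 lamina transcription factor genes did, also adjusted over the list alone. Each type had a factor at high level: svp in L1 (49.7 ± 6.36 RPKM; 0.0955 to 0.852 in the others), bab2 in L2 (69.0 ± 7.45; 0.269 to 2.09), erm in L3 (204 ± 53.3; 0.0930 to 1.46), ap in L4 (21.9 ± 0.393; 0.520 to 1.57) and pdm3 in L5 (374 ± 69.8; 0.486 to 5.11). Other factors were shared, such as the homeobox gene bsh in L4 and L5 (509.6 ± 51.2 and 304 ± 49.5), zfh1 in L1 and L3 (14.9 ± 1.02 and 15.8 ± 4.03) and sim in all but L5 (0.0331 ± 0.0128 in L5, 15.7 to 18.2 in the others). Requiring more than a 2-fold difference from the other 4 types left 356 genes for L1, 376 for L2, 580 for L3, 551 for L4 and 461 for L5.

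L1 was the glutamatergic type by transcript. VGlut (FBgn0031424), the vesicular glutamate transporter, stood at 217 ± 4.34 RPKM in L1 and at 0.354 to 4.95 in L2 to L5 (log2 difference 6.46 ± 0.39 SE, adjusted p = 1.21e-07). The other genes named were the cytochrome P450 gene Cyp313a5 (FBgn0038005; 7.01), CG14086 (FBgn0036860; 6.59) and hig (FBgn0010114; 5.59), whose product resides in the synaptic cleft, at 1127 ± 52.3 RPKM. Of the 70 guidance and surface genes, Lar, a receptor phosphatase that photoreceptor axons use in targeting, was at 504 ± 16.5 RPKM in L1 (19.3 to 100.04 in the others), though 83.6% of its exonic bases overlap another gene on the same strand. Fas1 (311 ± 5.92; 29.0 to 67.2) and CadN (491 ± 52.7; 40.4 to 248) were also higher in L1. Synaptic release genes were higher in 8 of 17 cases and lower in 0 (9 and 0 over the list alone; camera adjusted p = 0.000967, and adjusted p = 0.855 with an estimated correlation), but in 5 without L1 replicate 1 and in 3 without L1 replicate 2. Beat and side genes were higher in 4 and lower in 8 of 19 cases (4 and 9; camera adjusted p = 0.0250, and adjusted p = 0.855 with an estimated correlation). In all 891 genes were higher and 1080 lower, and quantile normalization, which moved the median difference of all genes from -0.10 to 0.02, gave 1251 and 932. The count of higher genes was 426 without L1 replicate 1 and 392 without L1 replicate 2.

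L2 had 1120 genes higher and 896 lower than the other 4 types, and a surface gene led them. CG14372 (FBgn0038156; side-IV), a Side family surface gene, was at 181 ± 20.001 RPKM in L2 and 0.495 to 4.99 in the others (log2 difference 5.97, adjusted p = 1.54e-10), and 50.01% of its exonic bases overlap an opposite-strand gene. CG13739 (FBgn0033403; 5.81) and the odorant receptor gene Or45a (FBgn0033404; 5.18) followed, with CG33993 (FBgn0053993; Egfrap; 5.64). Bab1 stood at 85.7 ± 29.1 RPKM, the dopamine receptor gene DopR at 27.9 ± 9.09 (0.584 to 2.87 in the others) and the secreted guidance gene sli at 27.0 ± 4.10 (0.123 to 1.05). The factor gene dac was lower in L2 (log2 difference -6.10). Of 30 receptor genes, 13 were lower in L2 and 2 higher (14 and 3 over the list alone; camera adjusted p = 8.92e-06, and adjusted p = 0.202 with an estimated correlation), and 1 was higher without L1 replicate 2, either L2 replicate or L5 replicate 1. The count of higher genes was 564 without L2 replicate 1 and 285 without L2 replicate 2, and 685 in a fit on the lamina libraries alone.

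L3 was marked by dpr17 (FBgn0051361), a member of the dpr family of surface proteins, at 354 ± 20.7 RPKM against 0.374 to 2.05 in the other lamina types (log2 difference 7.61 ± 0.12 SE, adjusted p = 3.75e-13). The zinc finger gene erm (FBgn0031375; 7.09) and the secreted guidance gene NetB (FBgn0015774; 409.7 ± 83.6 RPKM; 7.06) came next, with CG33673 (FBgn0053673). NetB's relative NetA was at 11.04 ± 4.34 RPKM in L3 and 0.0399 to 1.30 in the others, and Fas3 at 159 ± 17.99 and 3.50 to 88.9. Of 70 guidance and surface genes 28 were higher and 13 lower (32 and 16 over the list alone; camera adjusted p = 0.000563, and adjusted p = 0.511 with an estimated correlation), and the receptor gene Tl was lower (-3.25). Photoreceptor identity genes were higher in L3 than in the other lamina types in 8 of 10 cases and phototransduction genes in 11 of 17 (9 and 12 over the list alone; camera adjusted p = 2.22e-05 and 3.33e-05, and adjusted p = 0.0530 and 0.0959 with an estimated correlation), at levels such as 45.5 ± 17.9 RPKM for chp. Of 30 receptor genes 16 were higher and 5 lower (16 and 6; camera adjusted p = 0.000104, and adjusted p = 0.248 with an estimated correlation), among them the muscarinic receptor gene mAChR-B (3.42), the nicotinic subunit gene nAChRalpha3 (2.81) and the octopamine receptor gene Oamb (2.66). In all 1166 genes were higher and 936 lower, and quantile normalization gave 1018 and 1493. Without L3 libraries 3 and 4, a choice made after seeing the data, 1876 were higher.

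L4 and L5 shared several genes and were told apart by others. In L4 the rule named CG9336 (FBgn0032897; bero; 6.47), CG42339 (FBgn0259241; vex), the signalling adaptor gene Traf4 (FBgn0026319; 6.17) and the neuropeptide gene Ast-C (FBgn0032336; 76.2 ± 2.44 RPKM in L4, at most 0.974 in another lamina type, and adjusted p = 2.24e-08). In L5 it named the neuropeptide gene Ptth (FBgn0013323), known for its control of ecdysone release, at 1104 ± 387 RPKM (0.109 to 16.3 in L1 to L4; 8.49, adjusted p = 1.11e-10), pdm3 (FBgn0261588; 7.09), CG6234 (FBgn0038071; Dtg; 6.45) and CG34371 (FBgn0085400; side-V). The GABA receptor gene Rdl was high in both types (1431 ± 896 RPKM in L4 and 1085 ± 252 in L5; 6.08 to 57.2 in the others), as were the glutamate receptor genes GluRIA (35.4 ± 8.17 and 89.4 ± 9.88) and GluRIB (56.0 ± 29.0 and 105 ± 28.4). The adhesion gene Fas2 was lower in L4 (15.5 ± 9.97 RPKM; 175 to 814 in the others), as was CadN (40.4 ± 5.00). Dscam3 was at 183 ± 41.1 RPKM in L5, and Lac was lower there (2.95 ± 1.06; 179 to 429.5 in the others). Stress genes were higher in L5 in 7 of 15 cases and lower in 0 (9 and 0 over the list alone; camera adjusted p = 6.94e-05, and adjusted p = 0.306 with an estimated correlation). Of the 7, 4 were copies of Hsp70, which are nearly identical and may share reads, and 2 of the 7 remained without L5 replicate 1. Of 5 blood cell genes tested, 3 were higher in L4 (1 without L4 replicate 2), with a list median of 1.26 log2 units (camera adjusted p = 0.0884, and adjusted p = 0.679 with an estimated correlation). They were Pxn, Cg25C and BM-40-SPARC, while Hml, nimC1, srp, He and eater did not pass the filter on low values. The potassium channel gene KCNQ was higher in L4 (4.42) and eag in L5 (4.19). In L4, 1078 genes were higher and 1147 lower, and in L5 802 and 831, the count of higher genes in L5 being 357 without L5 replicate 1.

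The dpr genes, whose products bind those of the DIP genes at the cell surface, were expressed at high levels in several types, and each type carried its own combination. At 10 RPKM or more, L3 expressed 14 of 21 dpr genes, L2 and L4 12, L1 and L5 10, R7 7 and R8 6. At 1 RPKM or more, L3 expressed 20, L4 and R7 17, L1, L2 and R8 15, and L5 14, so the photoreceptors were not lowest there. Of the 21, 17 differed among the 7 types (18 adjusted over the list alone). Most genes did so, 6623 of all 9346 tested. Some were nearly private to a type or pair of types, as dpr17 in L3, dpr15 in L1 (43.5 ± 6.37 RPKM; 6.82 in L3 and at most 0.423 elsewhere), dpr13 in L2 (118 ± 3.90; 16.1 in L4 and at most 3.47 elsewhere), dpr16 in L3 (26.1 ± 6.24; at most 1.31 elsewhere) and dpr1 in L3 and L4 (282 ± 38.8 and 298 ± 43.8; 40.2 in R7 and at most 10.0 elsewhere). Dpr3 was at 117 ± 5.69 RPKM in L3 and 21.6 ± 0.101 in L1, dpr12 at 94.5 ± 35.8 in L4 and 37.1 ± 0.952 in L2, and dpr6 at 89.8 ± 24.8 in L3 and 0.226 ± 0.0166 in L1. Others were broad: dpr7 ran from 116 to 191 RPKM over the 7 types, dpr19 from 21.7 to 30.6 and dpr21 from 45.6 to 121.

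Most dpr genes were lower in photoreceptors. Of 21, 14 were lower in R neurons and 2 higher (15 and 2 adjusted over the list alone; camera adjusted p = 0.000435, and adjusted p = 0.137 with an estimated correlation), with dpr14 at 27.1 to 37.5 RPKM in lamina types and 0.943 to 1.39 in R types. The 2 higher in R were dpr9 (2.14) and dpr11 (1.48). Among the 14 lower, dpr7 differed little and was not called without L3 replicate 1 (log2 difference -0.35, limma adjusted p = 0.0527). Without R8 replicate 2 its log2 difference was -0.26. Without the L3 libraries, dpr17 was not called different (log2 difference 0.11, adjusted p = 0.442), against -1.41 with them. R7 exceeded R8 in dpr1 (40.2 ± 1.39 and 10.0 ± 1.38 RPKM), dpr10 (12.03 ± 1.63 and 2.43 ± 0.208) and dpr11 (9.35 ± 1.44 and 2.72 ± 0.621), and R8 exceeded R7 in dpr8 (88.0 ± 11.5 and 38.8 ± 2.73) and dpr12 (4.25 ± 1.09 and 1.28 ± 0.126), although the call of dpr11 ended without R7 replicate 2 (adjusted p = 0.0578) or R8 replicate 1 (0.0546). Those of dpr8 and dpr12 ended without any single library of L1, L2, R7 or R8 (up to 0.253 and 0.284), and that of dpr8 also without L3 replicate 1 (0.0563). After quantile normalization 4 dpr genes were higher in R7 and 0 in R8. Among the lamina types, 9 dpr genes were higher in L3 and 5 lower (camera adjusted p = 0.00138, and adjusted p = 0.248 with an estimated correlation), and 3 were higher in L5 and 11 lower (camera adjusted p = 0.00116, and adjusted p = 0.306 with an estimated correlation).

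Between pairs of types, the number of dpr genes that differed ran from 5 for R7 and R8 to 16 for L3 and R7 and for L3 and R8. L1 and L2, with 781 differing genes the closest pair over all genes, differed in 12 dpr genes, and L4 and R8, with 4871 the most distant, in 13. The lowest count over the 21 pairs was 3 without a filter on low values or with a pseudocount of 0.1. It was also 3 without replicate 1 or 2 of L1, replicate 1 or 2 of L2, R7 replicate 1 or R8 replicate 2, and 2 without R7 replicate 2 or R8 replicate 1.

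**Figure D4:**
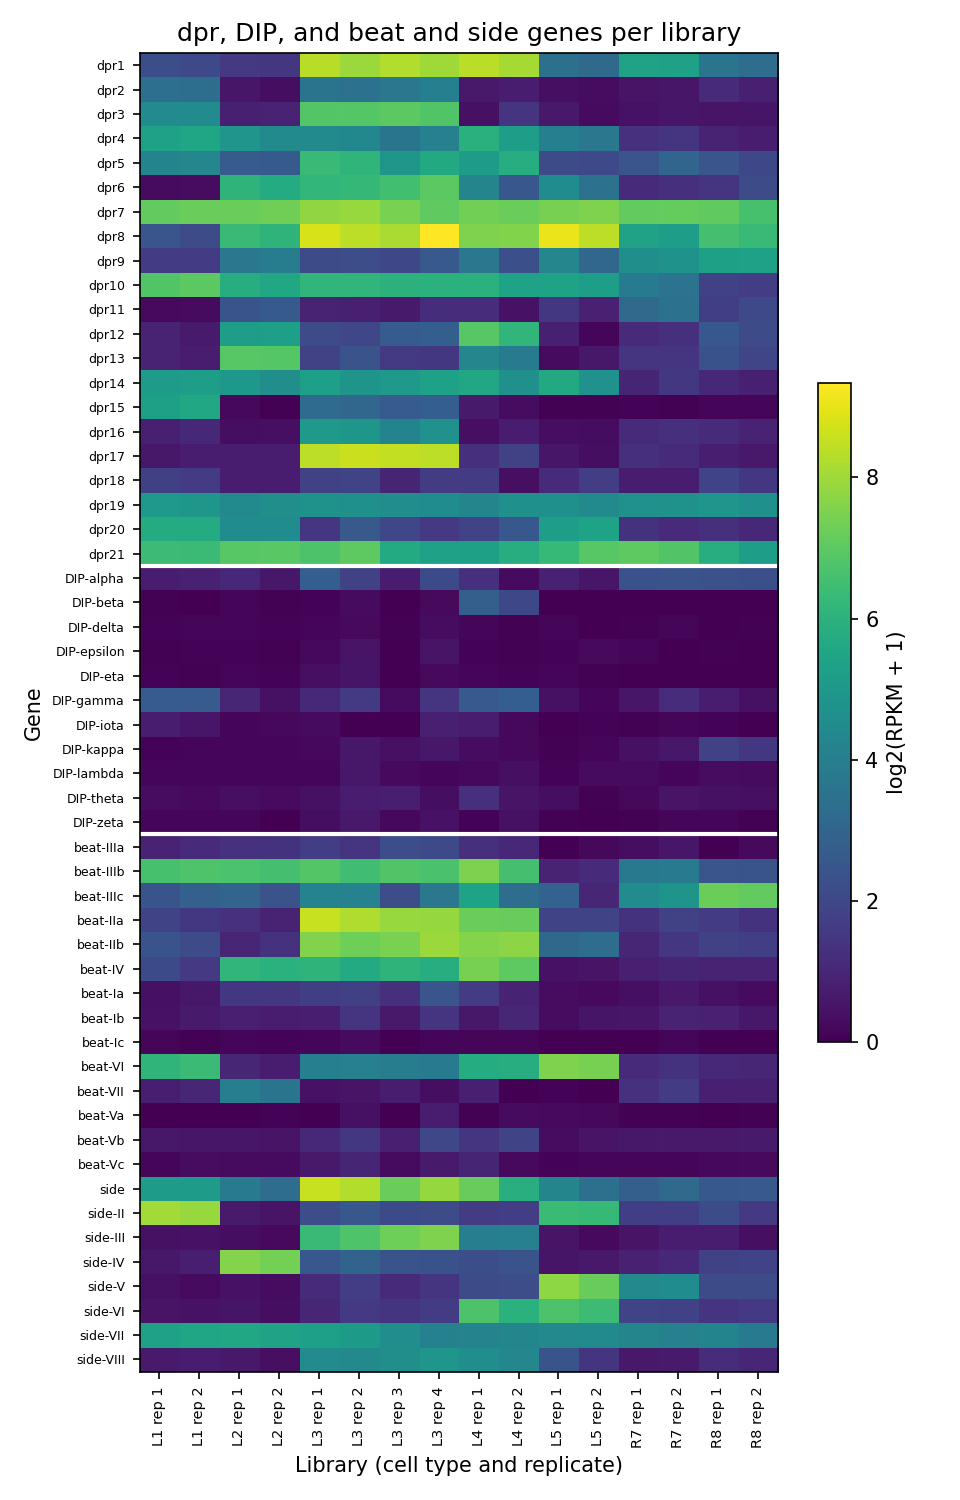
Heat map of log2(RPKM + 1) (colour scale from 0) for 21 dpr, 11 DIP, and 22 beat and side genes (y axis, families parted by white lines) in the 16 libraries (x axis). The L3 libraries stand out for dpr17, with a mean of 354 RPKM, and the DIP block stays dark, with no cell type mean at 10 RPKM.

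DIP transcripts were scarce in all 7 types. No DIP gene reached a mean of 10 RPKM in any of them, and 4 of 11 passed the filter on low values. All 4 differed among the types, also adjusted over the list alone, against 6623 of all 9346 genes tested. DIP-gamma stood at 5.49 ± 0.0173 RPKM in L1 and 5.46 ± 0.573 in L4 (0.225 to 1.26 in the others). DIP-beta was at 4.59 ± 2.11 in L4 (at most 0.113 in the others). DIP-alpha was at 4.18 ± 0.149 in R7 and 3.93 ± 0.0995 in R8 (0.637 to 3.09 in lamina types). DIP-kappa was at 2.16 ± 0.452 in R8 (at most 0.423 in the others). In R against L neurons 2 were higher and 2 lower (1 lower without R7 replicate 1). Between R7 and R8 the list's median difference was 0.03 and its mean -0.20, with 1 of 4 higher in R8.

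The beat and side genes, another pair of immunoglobulin families that bind each other, also divided the types. Of 19 tested, 18 differed among the 7 types, also adjusted over the list alone, against 6623 of all 9346 genes tested. Members at 10 RPKM or more numbered 11 in L4, 10 in L3, 6 in L2 and in L5, 5 in L1, 4 in R7 and 2 in R8. Those at 1 RPKM or more numbered 18 in L3, 17 in L4, 12 in R8, 11 in L2, L5 and R7, and 10 in L1. Among the side genes, CG42313 (side-II) was at 251 ± 17.1 RPKM in L1 and 78.6 ± 3.44 in L5, CG34113 (side-III) at 132 ± 47.6 in L3, side-IV at 181 ± 20.001 in L2, side-V at 179 ± 49.4 in L5 and 21.01 ± 1.47 in R7, and CG34114 (side-VI) at 83.1 ± 31.6 in L4 and 95.3 ± 15.3 in L5. Among the beat genes, beat-IIa was at 286 ± 67.2 in L3 and 146 ± 5.30 in L4, beat-IIb at 192 ± 39.6 and 203 ± 10.3, beat-VI at 177 ± 9.95 in L5 and 74.4 ± 8.98 in L1, and beat-VII at 12.97 ± 2.59 in L2. In R neurons 14 were lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.000108, and adjusted p = 0.126 with an estimated correlation), the 2 being beat-IIIc (144 ± 11.4 RPKM in R8, 24.8 ± 3.46 in R7) and side-V. In the R8 libraries side-V had 3.36 and 3.50 RPKM, near L4 (3.53 and 3.59) and far below L5. Its excess in R8 was thus over L1 to L3 only. Among lamina types 10 were higher and 4 lower in L4 (11 and 4; camera adjusted p = 0.000991, and adjusted p = 0.592 with an estimated correlation). Without L4 replicate 1, 2 were lower in L4, and without L4 replicate 2, 1 was. In L5 4 were higher and 10 lower (4 and 14; camera adjusted p = 0.00292, and adjusted p = 0.306 with an estimated correlation). Between pairs of types the count ran from 3 for R7 and R8 to 15 for L3 with L5, R7 or R8. Without any single R7 or R8 library the R7 and R8 count was 2.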

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

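Outlying libraries were sought by Dixon's test in the 4 L3 libraries, since other types had 2, over 67 named or listed genes. At the test's 95% critical value about 1 gene in 20 is expected to pass by chance, and 2 passed. NetB, the netrin that marks L3, stood at 533.687 RPKM in L3 replicate 1 and at 353 to 384 in the other 3 (gap over range 0.8292). VGlut stood at 11.8147 RPKM in L3 replicate 2 and at 2.40 to 2.87 in the other 3 (0.950), against 217 in L1. All 4 values of NetB lay above those of every other lamina library. No test was run on the cause of either.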

How the results depend on the processing

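The L3 omissions, the omission of genes that follow the Osiris family and voom on recovered reads were chosen only after the results were seen. The count-based tests in the plan were not run, because the values are RPKM. All 60 genes named by rule kept their direction and call in each alternative that tested them (58 in voom). The rule chose them for great differences without overlap between libraries, so this outcome was likely beforehand. Of 622 calls of list genes, 584 were kept under quantile normalization, 585 without a filter, 585 with a pseudocount of 0.1, 611 with a block and 479 in every leave-one-out fit. With 2 pooled classes 78 of 145 R against L calls were kept. Voom kept 526 of 576. Calls at a 2-fold threshold, fewer by construction, were 1420 higher and 1196 lower in R, 196 higher in R7, and 356, 376, 580, 551 and 461 higher in L1 to L5. Causes of the following were not tested. Pooled R and L classes gave 1842 lower in R. Replicate number as a block gave 588 higher in R7, 1866 in L2 and 2065 in L3, against 299, 1120 and 1166. Across 21 pairs of types, deviations correlated at -0.25 to 0.32 for replicates 1 (7 above 0.1) and -0.05 to 0.32 for replicates 2 (11 above), highest for R7 with R8. For pairs without L3 the values for replicates 1 and 2 are equal by construction, as deviations of 2 libraries mirror each other. Since not every pair passed 0.1, the numbers were not taken as pairs. The R7 and R8 libraries alone gave 1160 and 1319, the lamina libraries alone 685 for L2, and leaving out L3 libraries 3 and 4 gave 1876 for L3. Voom tested 8910 genes and called 2924 and 2549 in R against L and 271 and 581 in R7 against R8. The fewest dpr genes between 2 types were 3 without a filter and 3 with a pseudocount of 0.1. List shifts numbered 0 with an estimated correlation and 85 with fry, against 45.

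Signs reversed for dpr17 (0.11) and gogo (0.0947) in R against L without the L3 libraries, for svp in R against L (0.0897), beat-VII in L3 (0.58), svp in L3 (0.34) and erm in L4 (0.38) with voom, and for erm in L4 with a pseudocount of 0.1 (0.00507), with adjusted p from 0.417 to 0.993. The cause was not tested. Leaving out each library gave ranges of 2561 to 3111 higher and 2386 to 3040 lower in R, 136 to 373 higher in R7, 370 to 771 higher in R8, 3168 to 4737 among L1 to L5, and 392 to 1037, 285 to 1489, 939 to 1448, 834 to 1215 and 357 to 947 higher in L1 to L5. Across all 7 types it gave 5752 to 7095, with 17 to 19 dpr, 4 DIP and 18 beat and side genes, and 2 to 6 as the fewest and 15 to 17 as the most dpr genes between types. Highest counts came without L3 replicate 3 for R7 and for R8, and without L4 replicate 2 for L1, L2 and L5. Depth limits low values: 3 reads on a gene of 2 kb are 0.00977 to 0.0319 RPKM.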

Other observations

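Several genes outside the main comparisons varied strongly among types. Of the ecdysone response list, Blimp-1 (-2.41) and Eip75B (-1.91), a nuclear receptor gene, were lower in R than in L neurons, while Eip78C was lower in L1 than in the other lamina types (-4.33) and higher in L4 (1.91) and L5 (1.76). The small heat shock gene Hsp67Bc stood at 5322 to 7466 RPKM in lamina types and 404 to 555 in R types. The pigment transporter gene w was at 955 ± 144 RPKM in L1 and 41.2 to 279 in the other types, and its partner gene st was higher in R (3.57). The RNA-binding gene fne was lower in R (-4.82), the matrix gene SPARC higher in R (2.72), and the sex determination gene fru higher in L3 (2.07) and L5 (1.85). The rhodopsin Rh7 was at 67.8 ± 1.22 RPKM in L5 and 31.8 ± 0.219 in L1. The homeobox gene Optix was higher in R8 than in R7 (log2 R7 minus R8 -4.44).

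The tests below on photoreceptor genes in L3 and on Osiris genes were chosen only after the results were seen. The test of age and the splits of libraries were set beforehand. Exact 95% binomial intervals were added to the rules for the 2 percentages after their values were seen. By the rules as first written, with thresholds of 80% and 20%, the first percentage would have counted for its explanation and the second against. The 2 intervals include these thresholds. They treat genes as independent draws, which genes of the same libraries are not.

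The age field gives 96 h for R8 and the protocol 40 h for all. If R8 came from 96 h, near adult emergence, its opsins would be among the 100 most abundant genes, and if not, they would rank outside the first 1000. The best rank of Rh5 or Rh6 in an R8 library was 6972, with Rh6 at 1.74 RPKM. This is not consistent with an age of 96 h for R8, and it does not test the other ages.

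Photoreceptor genes stood in L3 at a median of 3.91% of their R level, and the question is whether this may come from photoreceptor RNA in the L3 samples. If so, the share would be similar from gene to gene, and 33 of 41 genes (80.4878%, exact interval 65.1 to 91.2%) lay within 3-fold of the median, and the interval includes 80%. This is left open for the genes as a set. A share of a few percent would not supply the levels of CG14795 (155% of the R level), bru-3 (118%), klg (99.2%) and pHCl (22.96%), the 4 genes above that range. For reads of R7 and R8 libraries assigned to L3, shares would be nearly a single number, but their 90th percentile was 8.10017 times the 10th, against the prediction of under 2 times. Expression by L3 itself was not tested. Without L3, 3218 and 3066 genes were called in R against L, and of 145 calls of list genes 135 were kept, 8 were lost and 2 changed sign.

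Osiris genes, most of them known from cuticle-forming epithelia, varied between libraries of a type, as between 0.625 and 49.9 RPKM (median of 17 genes) in L3. Their deviations correlated at a mean of 0.65987, against at most 0.251 in 100 random sets of genes matched on level and 0.589 in 100 matched on spread within types. The family was chosen because its members varied, so this does not test whether they vary together, and other cells or co-regulation in the neurons could produce it alike. The prediction was that most R8-higher genes would follow the family if other cells explained the R8 excess. Of 303 genes 57 did (18.8119%, exact interval 14.6 to 23.7%), against 6.63% of R7-higher genes and 6.25% of all genes. The interval lies below the predicted majority but includes the 20% set for the opposite outcome. However, deviations were taken from each type's mean, which removes any RNA present alike in both R8 libraries. The share thus cannot decide whether such cells account for the excess or a part of it, and this is left open. Without the followers 275 genes were higher in R7 and 523 in R8.

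Splits of the libraries asked how often arbitrary groups give as many genes, in a simpler fit with only 2 pooled groups, so its counts differ from those of the fit with 7 types. For R against L, 1 of 100 splits of the 16 libraries into 4 and 12, the real split itself, reached the real 4159 genes, and the highest other gave 1940. For L3, 2 of 100 splits of the lamina libraries into 4 and 8 reached the real 419 higher genes, the other being the 4 L1 and L2 libraries with 634, which is a structure of the samples. Most of these splits cut through cell types and gave a median of 0 genes, so they say little about chance. Splits that keep every type whole, added after the results were seen, number 16 and 7, too few for a share under 0.05. Among them the highest other for R against L was 698 (L4 with L5), and for L3 again 634.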
